A study of Arabidopsis thaliana with 21 samples.

How the data were processed

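Whole-genome expression was measured on ATH1 arrays in 21 RNA samples of Arabidopsis seedlings grown in the light in liquid culture for 7 days and treated for 1 h. The labels define 6 groups: the solvent DMSO (n = 4), 5 µM indole-3-acetic acid, the auxin IAA (n = 4), 10 µM of a compound named only A (n = 4), 10 µM of a compound named only B (n = 3), IAA with A (n = 3) and IAA with B (n = 3). The deposited table holds 1 log2 signal per probe set and array, and the method by which the authors summarised and normalised the probes is not given in the sources used here. The values ran from 3.02 to 13.9 and the array medians from 7.17 to 7.25, so no further log transformation and no pseudocount was applied. The labels do not say whether arrays of a group came from separate cultures, so the p-values may measure technical spread. The number of arrays limits the precision.

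Of 22810 probe sets, 64 control probe sets were left out and 22746 were tested. The table supplied with the data paired 13513 of the tested probe sets with 1 gene and 503 with several, and 8730 with none. Only probe sets paired with 1 gene are named by gene. Most list members therefore could not be measured, although the array may carry them. Counts within a list are out of its measured members only, and the missing ones include IAA1, IAA19, HSP70 and HSP101. Symbols came from the RefSeq gene table, and loci without a symbol are given by locus tag.

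A linear model with 1 mean per group was fitted to all 21 arrays with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean intensity. Fold changes are log2 differences between group means with their standard errors (SE), the tests are two-sided, and p-values were adjusted over the 22746 probe sets by the Benjamini-Hochberg method at a threshold of 0.05. The comparisons were IAA, A and B against DMSO, IAA with A and IAA with B against IAA alone, each combination against its compound alone, A against B, and IAA with A against IAA with B. The interaction of IAA with each compound, which is the IAA response in the presence of the compound minus the IAA response without it, and the difference between both interactions were tested in the same model.

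On simulated data with 200 of 22746 probe sets changed, the model recovered 97.0% of changes of 1 log2 unit in IAA against DMSO, with 7 false calls. For the interaction of IAA with A it recovered 28.4% of changes of 0.5, 85.1% of changes of 1 and all changes of 2 log2 units, with 10 false calls. For the interaction of IAA with B these shares were 22.4%, 83.6% and 98.5%, with 8 false calls. The simulated noise was independent between probe sets and of equal spread in all groups, so these rates may not carry over to the arrays.

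Lists of genes, 21 in all with 374 genes, were written before the data were examined. They covered Aux/IAA repressors, GH3 amido synthetases, SAUR genes, ARF factors, the auxin receptor machinery, auxin transport, LBD and HD-ZIP II factors, ethylene, brassinosteroid and gibberellin, cytokinin, cell wall, indole metabolism, xenobiotic detoxification, heat shock, touch and rapid stress, jasmonate, abscisic acid, the 26S proteasome, the circadian clock, and root and shoot markers. The 10 lists with at least 3 measured members were tested with camera from limma at a preset inter-gene correlation of 0.01, and again with an estimated correlation. In 50 simulations, camera called the shifted list in 50, and it called 6 of 450 unshifted lists, in 5 of the simulations. The simulated probe sets varied independently of each other, so this does not show the rate of false calls among correlated genes. For the Aux/IAA list a score, the mean log2 signal of its measured members, was compared between groups by two-sided exact permutation tests, adjusted over 9 comparisons.

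Genes were named by a rule fixed before the data were examined: in each comparison the 8 largest rises and the 8 largest falls past the threshold with 1 gene, every Aux/IAA or GH3 member past it, up to 4 members of each other list past it, and up to 2 members of a list with none past it. The text gives part of the genes so chosen. For the interactions, all probe sets past the threshold are given, including those without a gene. The set of IAA-responsive probe sets held those past the threshold and changed at least 2-fold in IAA against DMSO. Its median response was compared without and with each compound, with a jackknife SE over arrays. The correlation of the A and B effects was set against 50 simulations in which only the shared DMSO arrays linked both comparisons.

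The alternatives fixed before the data were examined were quantile scaling, the upper 60% of probe sets by mean signal, only the arrays of the groups compared, moderation without the intensity trend, array weights, a block for the replicate number, and leaving out each array in turn. For the IAA-responsive set they also included adjusted p 0.01, a 1.5-fold threshold, and selection on one part of the replicates with measurement on the other. For the Aux/IAA score they included the median, for the lists an estimated correlation, fry and all probe sets of a member, and for the overlap separate DMSO arrays for each compound. Chosen after the data were seen were a fit without DMSO 2, DMSO 4, A 2 and IAA plus B 1, a set of IAA-responsive probe sets chosen with the other compound, overlaps between comparisons that share no array, and tests of families of genes with a common symbol. A change of pseudocount did not apply to log2 values, and a block for the scan day was not possible because the date fields held no dates. The experiment files of the arrays were used only to check the treatments and chip lots. Raw probe intensities were not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.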

Results

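Expression of 22746 probe sets was compared between 6 groups of Arabidopsis seedlings treated for 1 h, with 4 arrays each for DMSO, IAA and compound A and 3 arrays each for compound B, IAA plus A and IAA plus B. The median SD of a probe set within a group was 0.15 log2 units in DMSO, 0.09 in IAA, 0.14 in A, 0.11 in B, 0.09 in IAA plus A and 0.11 in IAA plus B. The model pooled the spread over all groups. Its p-values against DMSO may therefore be too small, and those of the combinations against IAA alone too large. The lowest correlation between arrays of a group, taken across probe sets, which are not independent replicates, was 0.978 and lay in DMSO. The arrays farthest along the first component of the residuals were A 2, at -36.0, and DMSO 4, at 31.4. All list directions given as calls were the same after quantile scaling, which shifted the median fold change of each comparison by at most 0.02. Whether the values of a gene overlapped between groups is given for all probe sets beside the share that chance gives; for the genes named it only describes them, since they were chosen as past the threshold on the same arrays.

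The response to auxin was addressed by comparing IAA with DMSO (n = 4 each). IAA raised genes that conjugate auxin and genes that repress or transmit its signal. GH3.3, an enzyme that conjugates IAA to amino acids, rose by 4.91 ± 0.12 (SE) log2 units, or 30.1-fold (adjusted p = 5.66e-16), GH3.1 by 3.21 ± 0.19 and GH3.5 by 2.95 ± 0.17. LBD29, a transcription factor of lateral root initiation, rose by 3.9 ± 0.22, LBD16, which acts in the same process, by 1.86 ± 0.16, and the HD-ZIP II factor HAT2 by 2.93 ± 0.15. The Aux/IAA repressor genes IAA29 and IAA30 rose 13.5-fold and by 1.91 ± 0.17 log2 units. The small auxin-up RNA SAUR10 rose 8.99-fold, and AT4G35200 by 2.57 ± 0.21 log2 units. AT2G21560 fell by 1.39 ± 0.18 log2 units.

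By list, 2 of 7 measured Aux/IAA members rose (3 adjusted over the list alone; camera adjusted p = 8.58e-07), as did 3 of 5 GH3 members (3 adjusted over the list alone; 2.10e-14) and 3 of 3 LBD and HD-ZIP II members (3 adjusted over the list alone; 1.30e-18). Of 5 cell wall genes, 3 rose (3 adjusted over the list alone; 3.79e-06). They were XTH19, which remodels xyloglucan, by 1.17 ± 0.13, XTH18 by 0.94 ± 0.21 and EXPA4 by 0.76 ± 0.18; XTH18 lost the threshold without any one of 5 arrays and EXPA4 without any one of 6, and over the alternatives their adjusted p reached 0.258 and 0.203. These 4 list calls held with an estimated correlation, at adjusted p up to 0.0052. The other 6 tested lists had 0 members past the threshold and no camera call, the lowest adjusted p being 0.0927 for root markers; adjusted over the list alone, 1 detoxification, 1 abscisic acid and 1 root gene were higher. The auxin transport kinase WAG2 had a log2 difference of 0.86 that missed the threshold (adjusted p = 0.0768).

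In all, 435 probe sets passed in IAA against DMSO, 326 higher and 109 lower, and 128 of the higher and 8 of the lower changed at least 2-fold. Of all probe sets, 7.59% had values that did not overlap between the groups, where chance gives 2.86%; of the genes named, XTH18 overlapped. The count fell to 246 without IAA 2, and to 212 when only the arrays of these groups were fitted. The mean Aux/IAA signal was 5.66 ± 0.08 (SD, n = 4) in DMSO and 6.57 ± 0.18 (SD, n = 4) in IAA, a difference of 0.91 (exact permutation p = 0.0286, the smallest this design allows, and 0.129 adjusted over 9 comparisons). Of the 7 members, IAA29 and IAA30, at 3.76 and 1.91, made up most of it, and the median over members differed by 0.50.

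**Figure D1:**
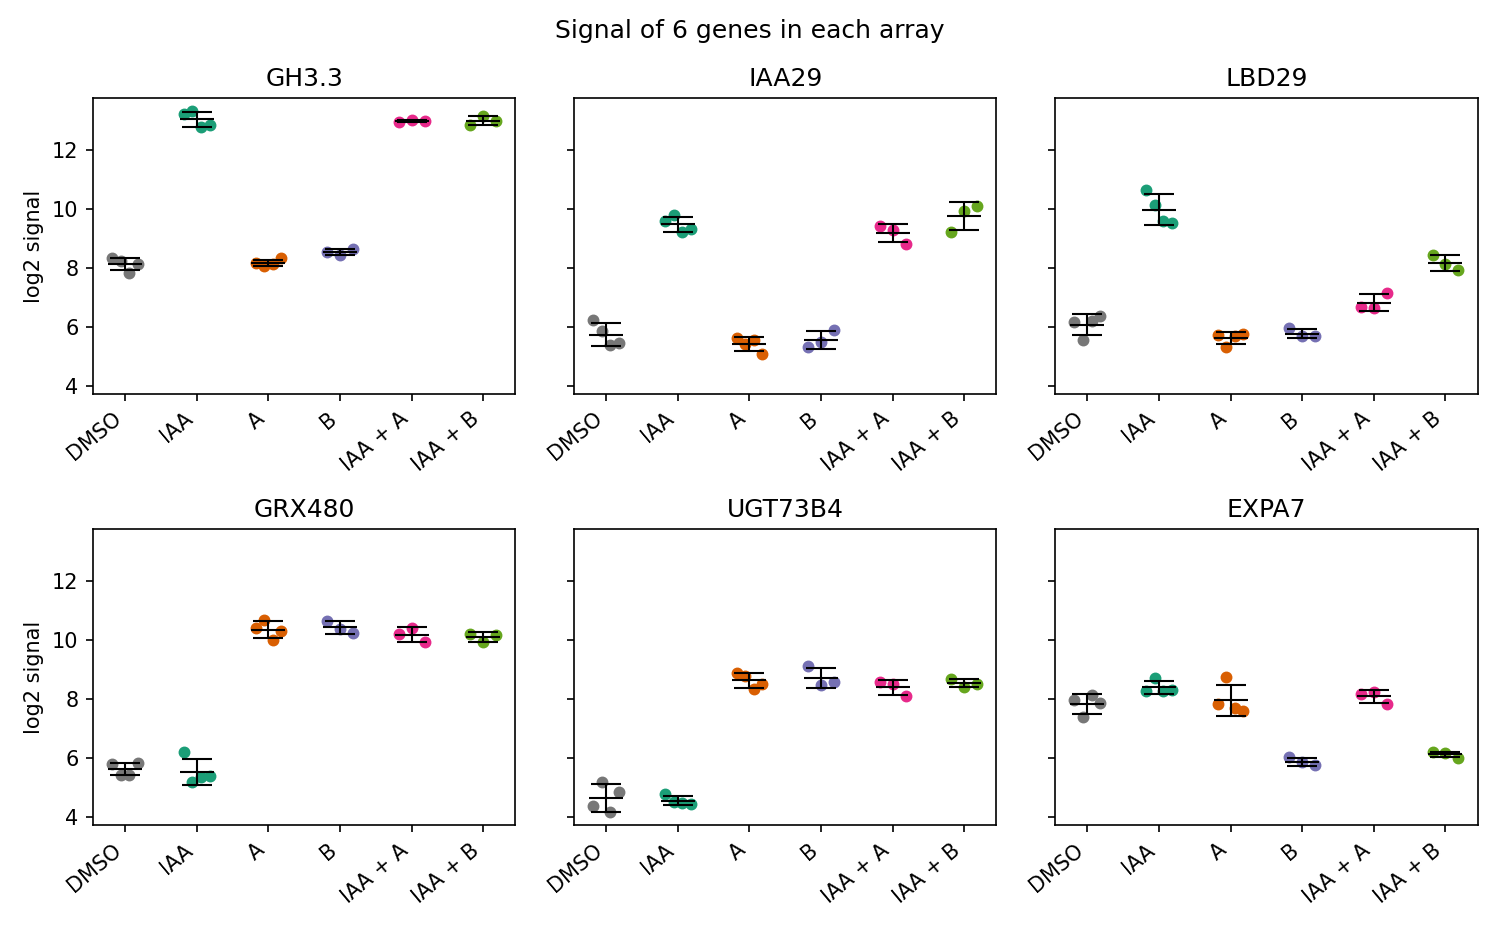
Log2 signal of GH3.3, IAA29, LBD29, GRX480, UGT73B4 and EXPA7 in each of the 6 groups. Points are arrays, lines are the group mean and SD; GH3.3 was 4.91 log2 units higher with IAA than with DMSO, and LBD29 had means of 9.98 with IAA, 6.81 with IAA plus A and 8.16 with IAA plus B.

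The effect of compound A without added auxin was addressed by comparing A with DMSO (n = 4 each). A raised genes of detoxification, heat shock and rapid stress. The glutaredoxin GRX480 rose by 4.74 ± 0.19 log2 units and the calmodulin-like gene CML37 by 4.52 ± 0.17. The glucosyltransferase genes UGT73B5 and UGT73B4 rose by 4.18 ± 0.24 and 3.99 ± 0.19, and the glutathione transferase genes GSTU25 and GSTU22 by 3.42 ± 0.17 and 2.62 ± 0.21. The small heat shock proteins HSP17.6C and HSP26.5 rose by 4.49 ± 0.47 and 4.25 ± 0.26, and the co-chaperone HOP3 by 3.31 ± 0.26. The zinc finger repressor ZAT10 rose by 2.94 ± 0.28 and the ubiquitin ligase PUB23 by 2.07 ± 0.26. WAG2, the only measured member of the auxin transport list, fell by 1.43 ± 0.24 log2 units (adjusted p = 0.000325). AT5G62360 stood at -2.18 ± 0.58 and lost the threshold without any one of 6 arrays, with an adjusted p of up to 0.128 over the alternatives.

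By list, 7 of 9 detoxification genes rose (7 adjusted over the list alone; camera adjusted p = 1.82e-13), 8 of 8 heat shock genes (8 adjusted over the list alone; 2.12e-18) and 4 of 5 touch and rapid stress genes (5 adjusted over the list alone; 3.13e-10), and these calls held with an estimated correlation at adjusted p up to 0.00581. Of the 5 cell wall genes 2 were lower (3 adjusted over the list alone), with no camera call (adjusted p = 0.168). They were EXPA15, at -0.55 ± 0.12, and XTH19, at -0.47 ± 0.13; over the alternatives their adjusted p reached 0.080 and 0.203, and XTH19 lost the threshold without any one of 5 arrays. None of the 7 Aux/IAA genes, 5 GH3 genes or 3 LBD and HD-ZIP II genes passed (0, 0 and 1 adjusted over the list alone), and their camera adjusted p was at least 0.172; the GH3 list had a median of 0.04 and a mean of -0.02. In the abscisic acid, proteasome and root lists 0 members passed (0 adjusted over each list alone), with adjusted p of at least 0.300.

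In all, 1909 probe sets passed in A against DMSO, 1240 higher and 669 lower. Of the higher 487 and of the lower 23 changed at least 2-fold. Of all probe sets, 9.21% had values that did not overlap between the groups, where chance gives 2.86%; of the genes named, AT5G62360 and XTH19 overlapped. The count was 2992 without A 2, 881 with only the arrays of these groups, and 4048 without DMSO 2, DMSO 4, A 2 and IAA plus B 1. The excess of higher over lower did not hold in that last fit (1984 higher, 2064 lower) or with array weights (1813 and 1865), and was smaller after quantile scaling (1208 and 965). A regrouping of the 8 arrays that exchanged A 2 and DMSO 4 called 3030 probe sets, more than the labelled groups.

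The effect of compound B was addressed by comparing B (n = 3) with DMSO (n = 4). Detoxification, heat shock and rapid stress genes rose here too: GRX480 by 4.82 ± 0.20, GSTU25 by 4.19 ± 0.18, UGT73B4 by 4.09 ± 0.21, GSTU22 by 3.61 ± 0.23 and ZAT10 by 2.66 ± 0.30 log2 units. HSP26.5 rose by 4.31 ± 0.29 and HSP23.5 by 2.50 ± 0.29. The expansins of root hairs fell, EXPA18 by 2.50 ± 0.31 and EXPA7 by 1.96 ± 0.22, and so did 3 class III peroxidase genes that the naming rule picked among the largest falls, a family for which no list was tested. AT1G34510 fell by 3.5 ± 0.56 although DMSO 2 held a low value, AT4G26010 fell by 3.31 ± 0.40 and AT1G30870 fell by 2.44 ± 0.31. GH3.17 fell by 1.06 ± 0.22 and GH3.5 by 0.79 ± 0.18, whereas GH3.3 rose by 0.41 ± 0.13 (adjusted p = 0.0486).

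By list, 7 of 9 detoxification genes rose (7 adjusted over the list alone; camera adjusted p = 4.50e-14), 7 of 8 heat shock genes (8 adjusted over the list alone; 8.39e-12) and 4 of 5 touch and rapid stress genes (4 adjusted over the list alone; 4.58e-08). Of 3 root markers, 2 fell (3 adjusted over the list alone; 5.54e-05), and the third, the root glucosidase PYK10, had a log2 difference of -0.16. The root-abundant lectin genes JAL33 and JAL34, chosen after their values were seen, had differences of -0.43 and -0.27 that missed the threshold. These 4 calls held with an estimated correlation, at adjusted p up to 0.0235. In the GH3 list, with 1 member higher and 2 lower (1 and 2 adjusted over the list alone), the median was 0.16 and the mean -0.20, with no camera call (adjusted p = 0.712). GH3.3 lost the threshold without any one of 6 arrays, with an adjusted p of up to 0.199 over the alternatives. Single members passed in the Aux/IAA list (IAA31, -0.55 ± 0.13), the LBD and HD-ZIP II list (HAT2, -0.54 ± 0.16) and the proteasome list (RPN2A, 0.31 ± 0.09), in each list 1 adjusted over the list alone, with camera adjusted p of at least 0.467. Over the alternatives the adjusted p of these 3 genes reached 0.0745, 0.286 and 0.153. In the cell wall and abscisic acid lists 0 members passed (0 adjusted over the list alone; both 0.749).

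In all, 1991 probe sets passed in B against DMSO, 907 higher and 1084 lower, and 371 and 218 of them changed at least 2-fold. The groups did not overlap for 16.9% of all probe sets, where chance gives 5.71%. With only the arrays of these groups the count was 1080, with 563 higher and 517 lower, so that the larger share changed sides. The mean Aux/IAA signal differed from DMSO by -0.11 in A (exact permutation p = 0.0857) and by -0.09 in B (exact permutation p = 0.229).

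**Figure D2:**
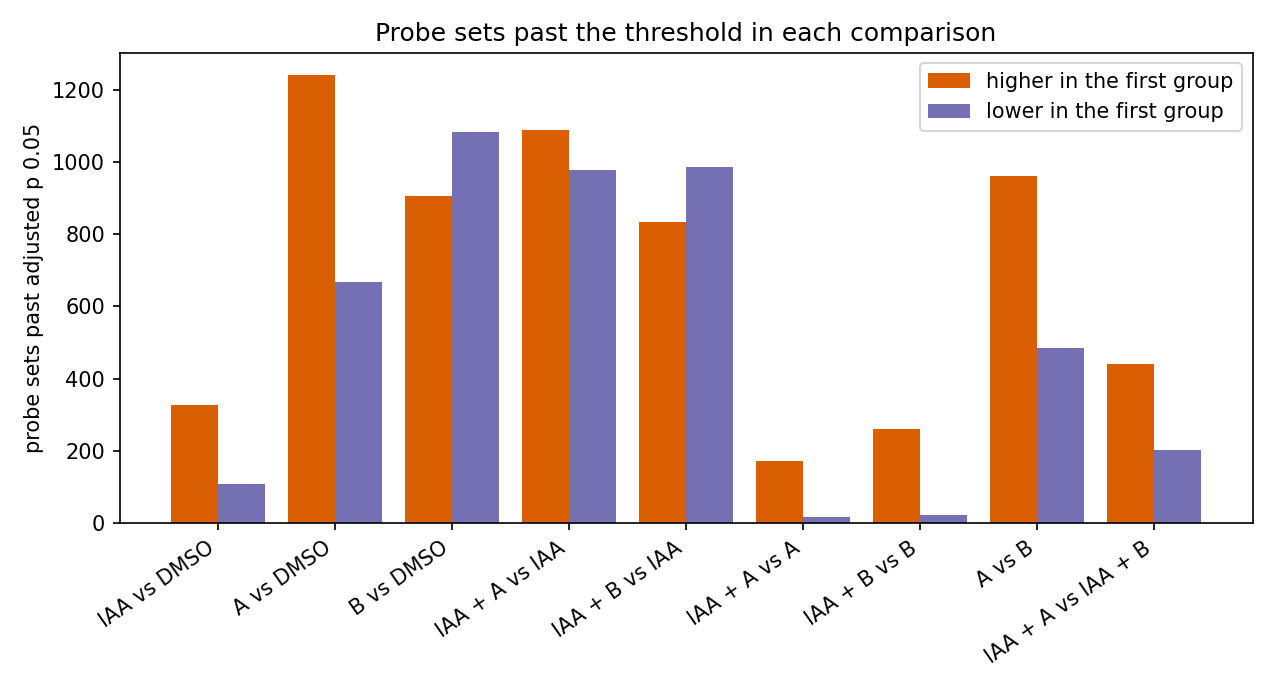
Number of probe sets higher (orange bars) and lower (purple bars) in the first group named, past an adjusted p of 0.05, in each of the 9 comparisons between groups. IAA against DMSO had 326 higher and 109 lower, and each compound against DMSO had over 4 times as many in all (1909 and 1991).

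Whether A changes expression in the presence of auxin was addressed by comparing IAA plus A (n = 3) with IAA (n = 4). LBD29 fell by 3.16 ± 0.23 log2 units (adjusted p = 7.64e-09), LBD16 by 0.91 ± 0.17, AT4G35200 by 2.57 ± 0.22 and AT1G64405 by 2.75 ± 0.24. Stress genes rose here too: GRX480 by 4.66, HSP17.6C by 4.43 ± 0.51, CML37 by 4.17 and UGT73B4 by 3.85. The cold-regulated and clock-controlled gene COR27 fell by 2.32 ± 0.61, and AT1G07050 by 2.48 ± 0.63; they lost the threshold without any one of 4 and of 2 arrays, and over the alternatives their adjusted p reached 0.0657 and 0.060. The clock gene GI, with a log2 difference of -0.75, did not pass (adjusted p = 0.218).

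By list, 7 of 9 detoxification genes rose (8 adjusted over the list alone; camera adjusted p = 4.60e-14), 8 of 8 heat shock genes (8 adjusted over the list alone; 5.74e-18) and 4 of 5 touch genes (5 adjusted over the list alone; 8.86e-11), which held with an estimated correlation at adjusted p up to 0.00639. Of the 3 LBD and HD-ZIP II genes, 2 fell (2 adjusted over the list alone; 0.00131), with an adjusted p = 0.0597 with an estimated correlation. In the GH3 list 1 member was higher and 2 were lower (1 and 2 adjusted over the list alone; 0.488): GH3.9 at 0.42 ± 0.12, GH3.1 at -0.72 ± 0.21 and GH3.5 at -0.63 ± 0.18. Each lost the threshold without any one of 4 or 5 arrays, with adjusted p of up to 0.182, 0.166 and 0.114 over the alternatives. Of 3 abscisic acid genes, 1 was lower (2 adjusted over the list alone; 0.0687), COR15B at -0.29 ± 0.08, and of 5 cell wall genes 1 (1 adjusted over the list alone; 0.218), EXPA15 at -0.54 ± 0.13. Their adjusted p reached 0.142 and 0.0836 over the alternatives. Of the Aux/IAA, proteasome and root genes 0 passed (0 adjusted over each list alone; at least 0.376).

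In all, 2065 probe sets passed, 1088 higher and 977 lower, with 463 and 78 changed at least 2-fold. The groups did not overlap for 31.3% of all probe sets, where chance gives 5.71%; of the genes named, GH3.1 overlapped. The count was 1225 without IAA plus A 1, 4661 with only the arrays of these groups and 3758 without the 4 arrays DMSO 2, DMSO 4, A 2 and IAA plus B 1. Lower probe sets were then the majority, 2764 against 1897 and 2141 against 1617, as they were with array weights (4213 against 2457) and with a replicate block (1298 against 1278). The mean Aux/IAA signal differed by -0.05 (exact permutation p = 0.743).

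The same question for B was addressed by comparing IAA plus B (n = 3) with IAA (n = 4). LBD29 fell by 1.82 ± 0.23 log2 units (adjusted p = 2.14e-05). GRX480 rose by 4.58, UGT73B4 by 3.99, CML37 by 3.76 and HSP26.5 by 3.46 ± 0.29. AT1G34510 fell by 4.28 ± 0.56, EXPA18 by 2.55 ± 0.31 and EXPA7 by 2.28 ± 0.22. Among the Aux/IAA genes, IAA30 was higher by 0.74 ± 0.18 and IAA31 stood at -0.49 ± 0.13; they lost the threshold without any one of 2 and of 3 arrays, and over the alternatives their adjusted p reached 0.0517 and 0.130.

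By list, 6 of 9 detoxification genes rose (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 4.24e-13), as did 4 of 5 touch genes (4 adjusted over the list alone; 4.80e-09), and 2 of 3 root markers fell (3 adjusted over the list alone; 1.54e-05). These held with an estimated correlation, at adjusted p up to 0.0171. Beside them, JAL33 and JAL34 fell by 0.55 and 0.41 (adjusted p = 0.0174 and 0.044). Of 8 heat shock genes, 7 rose (7 adjusted over the list alone; 4.80e-09), with an adjusted p = 0.0552 with an estimated correlation. Of 7 Aux/IAA genes 1 was higher and 1 lower (2 and 1 adjusted over the list alone; 0.429). Of 3 LBD and HD-ZIP II genes 1 fell (1 adjusted over the list alone; 0.429), and their median was 0.17 and their mean -0.46. Of 5 GH3 genes 0 passed (2 lower adjusted over the list alone; 0.2), of 5 cell wall genes 0 (0 adjusted over the list alone; 0.443), of 4 proteasome genes 1 (1 adjusted over the list alone; 0.2) and of 3 abscisic acid genes 1 (2 adjusted over the list alone; 0.0690). The last pair were RPN2A, at 0.30 ± 0.09, and COR15A, at -0.22 ± 0.07, which lost the threshold in most alternatives, with adjusted p of up to 0.207 and 0.179.

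In all, 1821 probe sets passed, 835 higher and 986 lower, with 335 and 232 changed at least 2-fold. The groups did not overlap for 24.8% of all probe sets, where chance gives 5.71%. With only the arrays of these groups the count was 2862. The mean Aux/IAA signal differed by 0.14 (exact permutation p = 0.343).

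Whether auxin still acts in the presence of a compound was addressed by comparing IAA plus A (n = 3) with A (n = 4), and IAA plus B with B (n = 3 each). With A present, IAA raised GH3.3 by 4.82 ± 0.13, IAA29 by 3.77 ± 0.23, HAT2 by 3.29 ± 0.16, GH3.5 by 2.37, GH3.1 by 2.34, IAA30 by 2.02 and WAG2 by 1.54 ± 0.26 log2 units. LBD29 rose by 1.20 ± 0.23 (adjusted p = 0.00982, and up to 0.0807 over the alternatives, without IAA plus A 3). With B present, IAA raised GH3.3 by 4.46 ± 0.14, IAA29 by 4.19, HAT2 by 3.72, SAUR10 by 3.65, GH3.5 by 3.22, LBD29 by 2.39 ± 0.25, IAA30 by 2.24 and LBD16 by 1.90.

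By list with A present, 2 of 7 Aux/IAA genes rose (3 adjusted over the list alone; camera adjusted p = 3.09e-11), 3 of 5 GH3 genes (3 adjusted over the list alone; 3.04e-19), 3 of 3 LBD and HD-ZIP II genes (3 adjusted over the list alone; 3.09e-15) and 1 of 5 cell wall genes, XTH19 (4 adjusted over the list alone; 6.06e-08). With B present, 3 of 7 Aux/IAA genes rose (5 adjusted over the list alone; 2.47e-11), 3 of 5 GH3 genes (3 adjusted over the list alone; 4.44e-18), 3 of 3 LBD and HD-ZIP II genes (3 adjusted over the list alone; 2.35e-19) and XTH19 of 5 cell wall genes (4 adjusted over the list alone; 4.25e-05). All 8 calls held with an estimated correlation, at adjusted p up to 0.0126. With B present, the 9 detoxification and 8 heat shock genes had negative medians, -0.31 and -0.86, with 0 members past the threshold (0 and 2 adjusted over the list alone; 0.00705 and 4.25e-05), and these calls were lost at adjusted p = 0.0998 and 0.150 with an estimated correlation. The other tested lists had 0 members past the threshold and 0 adjusted over the list alone in both comparisons, with camera adjusted p of at least 0.126. The touch list had a median of -0.05 and a mean of 0.06 with A, and a median of 0.02 and a mean of -0.08 with B.

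In all, 189 probe sets passed with A present, 172 higher and 17 lower, and 281 with B present, 260 higher and 21 lower. With array weights the first count was 683, with 366 higher and 317 lower, and without DMSO 2, DMSO 4, A 2 and IAA plus B 1 it had 198 higher and 52 lower. Of all probe sets, 8.64% with A and 14.8% with B had values that did not overlap between the groups, where chance gives 5.71% and 10.0%. A regrouping of the A and IAA plus A arrays that set A 2 with IAA plus A 1 and 2 called 209 probe sets. The mean Aux/IAA signal rose by 0.98 with A (exact permutation p = 0.0286, the smallest possible; 0.129 adjusted) and differed by 1.14 with B (exact permutation p = 0.1, the smallest possible).

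Whether a compound changes the auxin response was tested directly by the interaction. With A, LBD29 rose by 1.20 in place of 3.9 log2 units, an interaction of -2.70 ± 0.32 (adjusted p = 0.00118; n = 4 for DMSO, IAA and A and 3 for IAA plus A). The interaction passed for 11 probe sets, 1 positive and 10 negative, and all 11 had passed in IAA against DMSO. AT3G09280 rose by 1.42 with IAA alone and by 0.02 with A present (interaction -1.40 ± 0.17), and AT2G28690 by 1.46 and 0.12 (interaction -1.34 ± 0.18). With B the interaction passed for 3 probe sets, all negative and also called with A: AT2G28690, at -1.41 ± 0.18, AT4G37295, at -1.41 ± 0.23, and AT3G09280, at -1.28 ± 0.18. Over the alternatives their adjusted p reached 0.102, 0.235 and 0.146. Both interactions and IAA against DMSO use the same DMSO and IAA arrays, so calls shared between these tests are partly built in. Against DMSO the compounds alone changed AT4G37295 by 0.96 (A) and 1.25 (B), AT3G09280 by 0.39 and 0.36 and AT2G28690 by 0.01 and -0.25, and A alone changed AT5G64250, with an interaction of -0.80, by 2.44, so the smaller responses of AT4G37295 and AT5G64250 started from a higher level. The only positive interaction was that of AT3G21680, with means of 4.84 in DMSO, 4.16 in IAA, 4.09 in A and 4.06 in IAA plus A. A alone changed it by -0.75, so its smaller fall with IAA started from a lower level. A alone changed the called probe sets without a gene by -0.67, 0.09, -0.61 and 0.71. LBD29 had an interaction with B of -1.51 (95% interval -2.21 to -0.82) that did not pass (adjusted p = 0.243).

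Other strongly induced auxin genes gave interactions that did not pass. GH3.3 lay between 12.8 and 13.3 in all arrays with IAA, near the highest value of 13.9, where differences may be compressed. GH3.3 had -0.10 with A (95% interval -0.46 to 0.27) and -0.46 with B (-0.83 to -0.08; adjusted p = 0.831), and IAA29 had 0.01 with A (-0.65 to 0.67) and 0.44 with B (-0.25 to 1.12). GH3.1 had -0.87 with A (-1.46 to -0.27; adjusted p = 0.808) and -0.64 with B (-1.25 to -0.02), GH3.5 -0.57 with A (-1.09 to -0.06) and LBD16 -0.76 with A (-1.26 to -0.27). Of the 3 LBD and HD-ZIP II genes, 1 passed with A (2 adjusted over the list alone; camera adjusted p = 0.00283), with an adjusted p = 0.189 with an estimated correlation. With B, the Aux/IAA list was higher and the detoxification and heat shock lists were lower (camera adjusted p = 0.0466, 0.0452 and 0.0452), with 0 members past the threshold (0, 1 and 0 adjusted over the list alone) and an adjusted p = 0.313, 0.313 and 0.625 with an estimated correlation. The difference between both interactions passed for 0 probe sets in limma, with 782 at an unadjusted p under 0.05. In that difference LBD29 stood at -1.19 (95% interval -1.90 to -0.47), the LBD and HD-ZIP II list was lower (2 adjusted over the list alone; 7.90e-05) and the heat shock list higher (0 adjusted over the list alone; 0.0371), with an adjusted p = 0.0552 and 0.579 with an estimated correlation. The other tested lists had 0 members past the threshold, at most 1 in each direction adjusted over the list alone, and no camera call in any of the 3 tests, at adjusted p of at least 0.0763.

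With only the arrays of the 4 groups, or without DMSO 2, DMSO 4, A 2 and IAA plus B 1, the interaction with B called 0 probe sets and that with A called 6 and 5. Leaving out single arrays gave 5 (without IAA 1) to 26 (without IAA 3) probe sets with A and 1 (without B 2) to 10 (without DMSO 1) with B.

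The auxin response as a whole was compared over the 136 probe sets that changed at least 2-fold with IAA, 128 higher and 8 lower. Their median response in the direction of IAA was 1.5 log2 units alone, 1.19 with A and 1.53 with B. This was 79.4% ± 24 (jackknife SE) of the response with A and 102% ± 17 with B, each within its SE of the full response. With a 1.5-fold threshold for the set the share was 52.2% with A and 74.0% with B, so it depends on the threshold. The direction was the same as with IAA alone for 132 probe sets with A and 127 with B, and 82 and 95 passed the threshold again. The set was chosen on the same arrays that gave the response alone, which favours a lower share. Chosen on the other compound's comparison, the share was 96.4% with A and 125% with B. That choice leaves out probe sets whose response both compounds lowered, such as AT2G28690 and AT3G09280, which favours a higher share. Chosen on replicates 1 and 2 and measured on the others, the share was 100.6% with A and 126% with B. Chosen on replicates 3 and 4, it was 74.5% with A and 101.5% with B. The IAA arrays were not alike in strength. Over 94 IAA-induced probe sets, IAA 1 and IAA 2 stood at 119% and 131% of the rise to IAA. IAA 3 and IAA 4 stood at 90.9% and 89.7%. The share was thus higher where the weaker arrays measured the response alone, so the splits do not isolate the effect of selection. The jackknife SE treats the IAA arrays as independent.

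**Figure D3:**
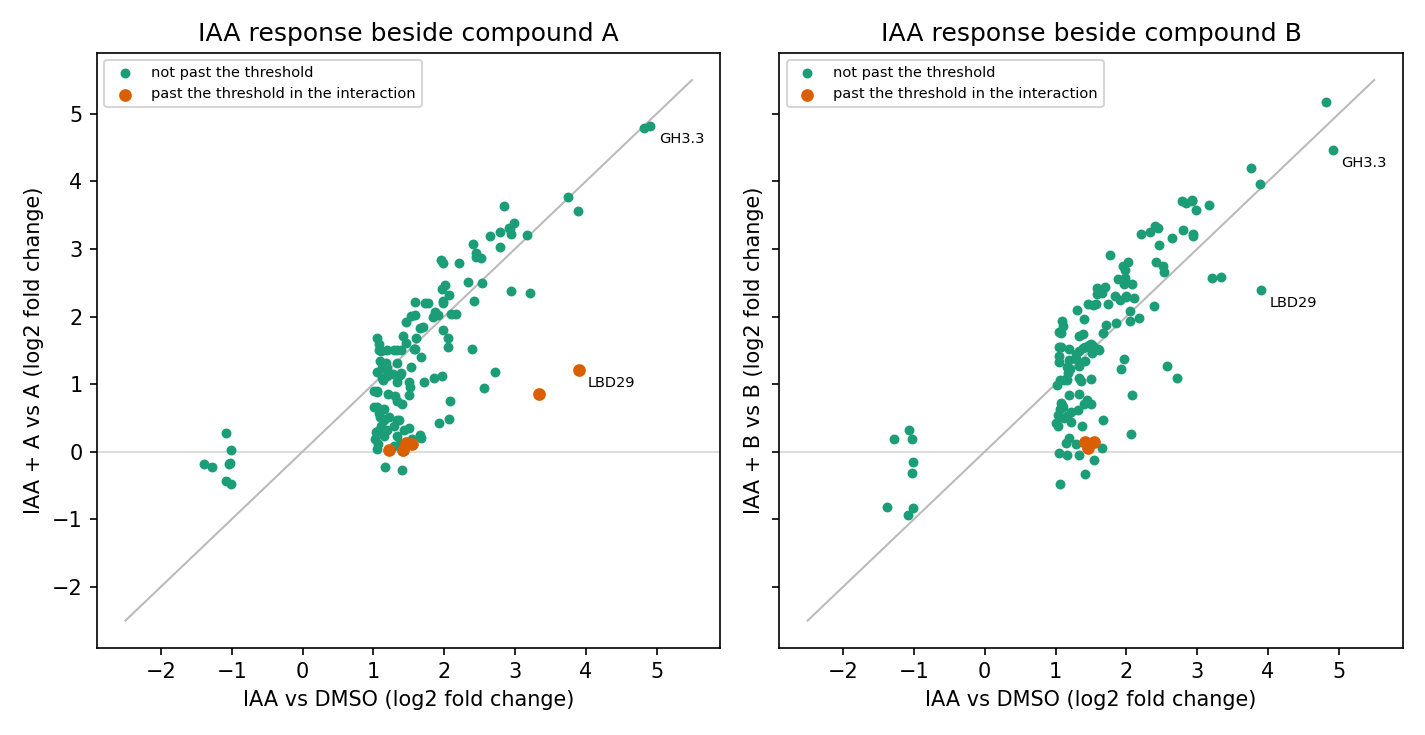
Response to IAA of the 136 IAA-responsive probe sets, in log2 units, without a compound (horizontal axis) and with A or B present (vertical axis). The diagonal marks an equal response and orange marks probe sets past the interaction threshold; LBD29 lies at 3.9 and 1.20 in the panel for A, and GH3.3 lies near the diagonal.

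The compounds, given at the same dose and time, were compared directly as A (n = 4) against B (n = 3), and with IAA present as IAA plus A against IAA plus B (n = 3 each). Without IAA, the peroxidase genes AT4G26010 and AT1G34510 and the root-hair expansins EXPA18 and EXPA7 were higher with A than with B: AT4G26010 by 3.41 ± 0.40, AT1G34510 by 3.2 ± 0.56, EXPA18 by 2.25 ± 0.31, with its highest value in A 2, and EXPA7 by 2.09 ± 0.22 log2 units. AT1G22810 was higher with A by 3.24 ± 0.13 and HOP3 by 1.71 ± 0.29 (1.15 ± 0.32 for ROF2, with an adjusted p of up to 0.205 over the alternatives), and AT2G41730 was lower with A, at -3.03 ± 0.28. GSTU22 and GSTU25 were lower with A, at -0.99 ± 0.23 and -0.77 ± 0.18, with adjusted p of up to 0.072 and 0.0636 over the alternatives. Of other genes that rose with both compounds, 3 had differences near 0: GRX480 -0.08 (95% interval -0.50 to 0.35), UGT73B4 -0.09 (-0.53 to 0.34) and HSP26.5 -0.06 (-0.65 to 0.54). These 3 lay outside the naming rule for this comparison. UGT73B5 had 0.27 (-0.27 to 0.82) and ZAT10 0.29 (-0.34 to 0.92). HSP17.6C had 1.70 (0.64 to 2.76; adjusted p = 0.0506) and CML37 0.52 (0.14 to 0.90; adjusted p = 0.0964), which missed the threshold with intervals that excluded 0.

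With IAA present, AT1G34510 was higher with A by 3.61, AT4G26010 by 3.04, AT1G22810 by 2.77, EXPA18 by 2.08 and EXPA7 by 1.97. LBD29 was lower with A than with B, at -1.34 ± 0.25 (adjusted p = 0.00483), and so was LBD16, at -1.08 ± 0.19 (adjusted p = 0.0029). HSP17.6C was higher with A by 2.55 ± 0.54, with an adjusted p of up to 0.0779 over the alternatives.

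By list without IAA, 2 of 3 root markers were higher with A (2 adjusted over the list alone; camera adjusted p = 0.000323), as were 2 of 8 heat shock genes (4 adjusted over the list alone; 0.000887), with an adjusted p = 0.0879 and 0.568 with an estimated correlation. Of 9 detoxification genes 2 were lower with A (2 adjusted over the list alone; 0.243). Single members passed among the GH3 genes (GH3.5 higher with A, 0.74 ± 0.18) and the cell wall genes (EXPA15, -0.55 ± 0.13), with adjusted p of up to 0.0927 and 0.105 over the alternatives (2 higher and 1 lower, and 1 lower, adjusted over the list alone; 0.445 and 0.243). With IAA, 2 of 3 root markers were higher with A (2 adjusted over the list alone; 2.60e-05), which held with an estimated correlation (adjusted p = 0.0486). Of 8 heat shock genes 5 were higher with A (5 adjusted over the list alone; 4.29e-08), with an adjusted p = 0.0856 with an estimated correlation. Of 3 LBD and HD-ZIP II genes 2 were lower with A (2 adjusted over the list alone; 0.000289), with an adjusted p = 0.0615 with an estimated correlation. The remaining lists had 0 members past the threshold, at most 1 adjusted over the list alone, and camera adjusted p of at least 0.157.

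In all, 1448 probe sets differed between A and B, 962 higher and 486 lower with A, and 642 with IAA present, 440 higher and 202 lower. Of all probe sets, 17.0% (chance 5.71%) and 25.2% (chance 10.0%) had values that did not overlap between the groups; of the genes named, ROF2 overlapped in the first. The first count was 485 without B 3, 602 with only the arrays of these groups and 2771 without DMSO 2, DMSO 4, A 2 and IAA plus B 1. The second was 243 without IAA plus A 1 and 2076 without the same 4 arrays, when 1014 were higher and 1062 lower, and with array weights 1560 were higher and 1958 lower. The mean Aux/IAA signal differed by -0.03 (exact permutation p = 0.743) and by -0.19 (exact permutation p = 0.2, where the design allows no less than 0.1).

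How far A and B act on the same genes was addressed by the overlap of their effects against DMSO. Higher with both were 633 probe sets, where independent lists would share 49.4, and lower with both were 219, against 31.9, while 4 went in opposite directions. Both comparisons share the DMSO arrays. Comparisons that share no array, A against DMSO with IAA plus B against IAA and B against DMSO with IAA plus A against IAA, had 704 and 728 probe sets changed in the same direction. Across probe sets, which are not independent replicates, the fold changes of A and B correlated at r = 0.704, against a median of 0.462 in simulations without effects, where only the shared DMSO arrays linked them. The simulated arrays had equal spread in all groups, whereas DMSO varied more than B, so the simulated r may be too low. When each compound had its own DMSO arrays, r had a median of 0.521 (0.474 to 0.636 over 6 assignments).

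**Figure D4:**
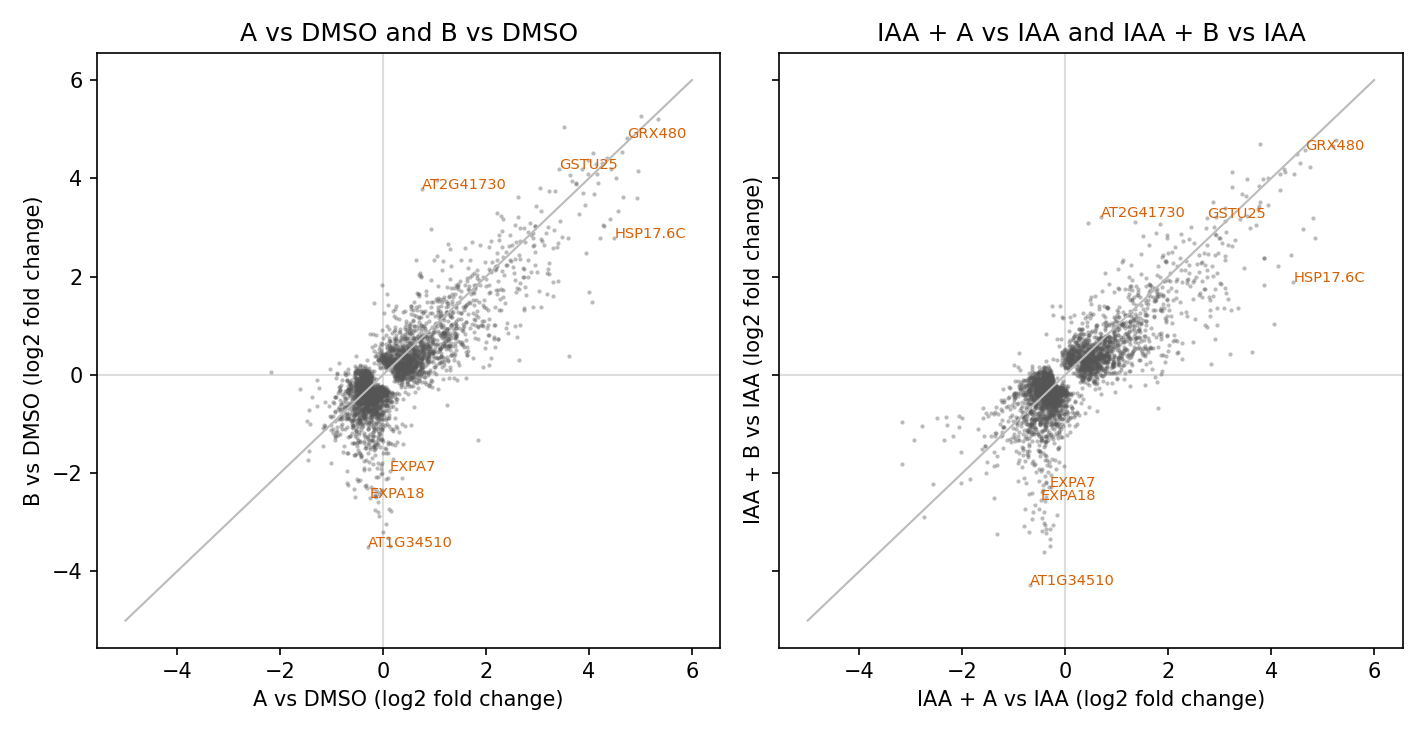
Log2 fold change with A (horizontal axis) against that with B (vertical axis), without IAA (left, against DMSO) and with IAA (right, against IAA), for probe sets past the threshold with either compound. Without IAA, 633 probe sets were higher and 219 lower with both; points far below the diagonal include the root-hair gene EXPA7, which fell by 1.96 log2 units with B.

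Of the lists with fewer than 3 measured members, SAUR10 and WAG2 passed over all probe sets only where given above (SAUR10 also in IAA plus A against A, at 3.21, and WAG2 also in IAA plus B against B, at 1.45, with an adjusted p of up to 0.0534 over the alternatives). The cytokinin response regulators ARR15 and ARR16, the auxin synthesis gene YUC2, the clock gene GI and the photosynthesis genes LHCB4.1 and RCA had 0 calls over all probe sets. Adjusted over the list alone, which for a list of 1 gene is no adjustment, both response regulators were higher in IAA plus B against B (median 0.41), 1 was lower in A and in B against DMSO and in IAA plus A against IAA plus B, and 1 was positive in the interaction with B. On the same terms YUC2 was lower in IAA and in B against DMSO (-0.20 and -0.22), GI was lower in IAA plus A against IAA (-0.75), and SAUR10 was lower in A against DMSO (-0.42) and in IAA plus A against IAA plus B (-0.58). WAG2 was higher in IAA against DMSO (0.86) and lower in B against DMSO (-0.71), IAA plus A against IAA (-0.74), A against B (-0.72) and IAA plus A against IAA plus B (-0.62). The lists of ARF factors, the auxin receptor machinery, ethylene, brassinosteroid and gibberellin, and jasmonate had 0 members with a probe set paired with 1 gene, so nothing is reported for them.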

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

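The tests of less root tissue, of the DMSO arrays, of the treatment of IAA 2 and of the time of harvest were chosen only after the results they concern were seen, while the counts over other splits of the arrays were planned.

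The IAA response differed with A for 11 probe sets and with B for 3, by the interaction test itself. With A the interactions were -2.70 for LBD29, -1.44 for AT4G37295, -1.40 for AT3G09280, -1.34 for AT2G28690, -0.80 for AT5G64250, -0.72 for AT5G51380 and 0.66 for AT3G21680, and -2.49, -1.20, -0.95 and -0.86 for 4 probe sets paired with no gene. With B they were -1.41 for AT2G28690, -1.41 for AT4G37295 and -1.28 for AT3G09280. Of the genes named in these tests, AT4G37295, AT5G64250, AT5G51380 and AT3G21680 with A and all 3 with B missed the threshold in some alternatives. AT3G21680 was already lower with A alone than with DMSO, by 0.75, so its positive interaction may reflect that lower start.

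In groups of 4 arrays, 1 array lay far from the other three for 15 of 186 combinations of gene and group, where chance gives about 1 in 20, or 9.3. Array A 2 held 6 of the 15: AT5G62360 at 8.37 (mean of the others 6.04), AT5G04960 at 9.02 (8.05), EXPA18 at 8.82 (7.75), GH3.17 at 8.38 (8.91), AT1G07050 at 5.23 (4.14) and COR27 at 6.35 (4.39). Array DMSO 4 held AT5G62360 at 7.05 (9.39), AT4G16146 at 5.84 (8.90) and AT5G51380 at 6.08 (6.21). IAA 2 held HSP23.5 at 7.80 (7.48) and EXPA7 at 8.73 (8.29). Single values were XTH19 in A 4 at 8.77 (8.23), AT1G34510 in DMSO 2 at 5.97 (9.13), COR15A in DMSO 3 at 4.14 (3.96) and AT2G41730 in DMSO 1 at 7.97 (6.79).

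The root-hair expansins EXPA7 and EXPA18 were lower with B, and the peroxidase genes AT1G34510 and AT4G26010 had the largest falls among named genes. Less root tissue in the B samples would lower other genes confined to roots by at least as much as EXPA7, which fell by 1.96. The root-abundant genes PYK10, JAL33 and JAL34 had a median of -0.27. PYK10, at 13.5 in DMSO, lies near the highest value of 13.9, where a fall may be compressed. JAL33 and JAL34, at 12.01 and 12.61, had 95% intervals that ended at -0.72 and -0.52. These values argue against a loss of root tissue as the whole cause only if these genes are confined to roots, which was not measured here. Otherwise such a loss stays open. A small fall stays open in any case, since JAL33 and JAL34 passed in IAA plus B against IAA. DMSO arrays that stand apart do not account for the lower values with B. Of the 218 probe sets at least 2-fold lower with B, 172, or 78.9%, were lower again in IAA plus B against IAA, which shares no array, against 4.33% of all probe sets. A response of these genes to compound B, fewer root hairs and other differences between the groups all stay open, and none of them was tested.

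The experiment file of IAA 2 describes 10 µM B, while the label and the other 20 files name the labelled treatment. RNA of seedlings given B would carry the B-induced genes, but over 143 such probe sets IAA 2 stood at 2.95% of the rise from DMSO to B, and over 94 IAA-induced probe sets at 131% of the rise to IAA. The values therefore argue against B in this array, and an error in the file text is a candidate explanation that no table tests.

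COR27, AT1G07050, AT4G16146 and AT2G39920 were lower in IAA plus A than in IAA, but AT4G16146 and AT2G39920 lost the threshold without any one of 7 arrays (adjusted p up to 0.218 and 0.141 over the alternatives), COR27 without any one of 4 and AT1G07050 without any one of 2. Arrays harvested at another time of day would also move the clock gene GI, by -1.11 at the slope seen within groups, and GI differed by -0.75 (95% interval -1.49 to -0.0045), which is consistent with a difference in harvest time although the interval only just excludes 0 and the adjusted p is 0.218. The same genes varied along the first component of the residuals, 32.0% of the residual variance, with A 2 and DMSO 4 at its ends. An effect of A on these genes stays open, since COR27 stood at -1.25 in A against DMSO without passing (adjusted p = 0.203). No times of harvest were given in the labels used here.

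Other splits of the same arrays were counted for each comparison. The split tests were not adjusted over comparisons, 1 of 35 is the smallest share that 35 splits can give, and arrays of a group that are not separate cultures would make them too lenient. On these terms, taking each comparison alone, chance can be excluded for IAA against DMSO (435 probe sets, highest other split 2; 1 of 35 splits as large), B against DMSO (1991, highest other 1080), IAA plus A against IAA (2065, highest other 354), IAA plus B against IAA (1821, highest other 431) and A against B (1448, highest other 310), each 1 of 35. For the interactions the residuals were redistributed among the arrays, which mixes groups of unlike spread (median SD 0.15 in DMSO and 0.09 in IAA). With that limit, the count for A exceeded every other draw (11, highest other 1, 1 of 100). It fell to 5 in the upper 60% of probe sets and to 6 with only the arrays of its groups. Since the redistribution takes the arrays as alike in spread, this argues against chance for A without excluding it. For B the count of 3 exceeded the highest other of 1, also 1 of 100. Yet the interaction with B called 0 in the upper 60% of probe sets and 0 with only the arrays of its groups. It also called 0 without DMSO 2, DMSO 4, A 2 and IAA plus B 1, so chance stays open for B. Chance cannot be excluded by this count for A against DMSO (1909, highest other 3030; 2 of 35) or for IAA plus A against A (189, highest other 209; 2 of 35). The split with 3030 probe sets exchanged A 2 and DMSO 4, which points to a structure of the samples besides treatment. That split and the one with 209 kept most arrays of each group together, so both still held part of the treatment difference. A against DMSO and IAA plus B against IAA, which share no array, both raised 546 probe sets, where independent lists would share 45.5. They lowered 158 in common, against 29.0, and 8 went in opposite directions. This argues against chance alone for these probe sets in A against DMSO. The structure is not a plain exchange of samples. A 2 stood at 99.4% and DMSO 4 at -0.51% of the rise in B-induced probe sets, as the labels of A and DMSO would have it. For the difference between the interactions the observed count was 0, which all 100 of 100 draws reach, so the comparison says nothing; the highest other draw gave 154. With 3 arrays against 3, the 10 splits are too few for IAA plus B against B (281, highest other 0; 1 split as large) and IAA plus A against IAA plus B (642, highest other 2; 1 split as large).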

How the results depend on the processing

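The fit without DMSO 2, DMSO 4, A 2 and IAA plus B 1, the set chosen with the other compound and the overlaps without a shared array were chosen after the results were seen. No count over a comparison changed by more than 1.5 times with quantile scaling or without the intensity trend. Of the 147 named results, 106 passed the threshold under every alternative run for them, 41 missed it under some and 0 reversed; 36 of the 147 lay outside the upper 60% of probe sets and were not run under that filter. The overlap of A and B was 852 probe sets, and 541 to 606 when each compound had its own DMSO arrays. Taking all probe sets of a list member changed nothing, since each measured member had 1. Signal over background was not measured here.

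With the upper 60% of probe sets the interactions called 5 (A) and 0 (B), and with a replicate block 19 and 7. Array weights gave 3678 (A against DMSO), 6670 (IAA plus A against IAA), 3670 (IAA plus B against IAA), 683 (IAA plus A against A), 3310 (A against B), 3518 (IAA plus A against IAA plus B), 21 and 10 (interactions). Without the 4 arrays the counts were 265 (IAA against DMSO), 4048 (A against DMSO), 3758 (IAA plus A against IAA), 2771 (A against B), 2076 (IAA plus A against IAA plus B), 5 and 0 (interactions). Only the arrays of the groups gave 212 (IAA), 881 (A) and 1080 (B) against DMSO, 4661 and 2862 (IAA plus A and IAA plus B against IAA), 602 (A against B), 6 and 0 (interactions) and 2 (their difference). In that last setting the comparisons with DMSO lost calls and those of the combinations with IAA alone gained calls. The wider spread in DMSO (median SD 0.15) than in IAA (0.09) would act in this direction. The causes of these changes were not tested.

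Over a 1.5-fold threshold the share of the IAA response was 52.2% with A and 74.0% with B. When replicates 1 and 2 chose the set it was 100.6% with A and 126% with B, and when replicates 3 and 4 chose it 74.5% and 101.5%; with the set chosen with the other compound it was 125% with B. The cause was not tested. The Aux/IAA difference was 1.92 for IAA against DMSO, 1.91 for IAA plus A against A and 2.1 for IAA plus B against B with the filter, which kept 2 of 7 members, and 0.50, 0.55 and 0.73 with the median. The median also turned B against DMSO from -0.09 to 0.022 and IAA plus A against IAA from -0.05 to 0.019. For the lists, an estimated correlation left 0 calls in A against B, 1 in IAA plus A against IAA plus B and 0 in both interactions and their difference. Fry called 1 in A against B and 0 in the interaction with B and the difference.

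Leaving out 1 array gave 246 (without IAA 2) to 437 probe sets for IAA against DMSO, 1413 to 2992 (without A 2) for A against DMSO, 1373 to 2132 for B against DMSO, 1225 (without IAA plus A 1) to 1544 for IAA plus A against IAA, 1262 to 1570 for IAA plus B against IAA, 133 to 187 for IAA plus A against A, 219 to 236 for IAA plus B against B, 485 (without B 3) to 1590 for A against B, 243 (without IAA plus A 1) to 712 for IAA plus A against IAA plus B, 5 to 26 and 1 to 10 for the interactions with A and B, and 0 to 11 (without IAA plus A 3) for their difference. The share of the response ran from 72.1% to 100.1% with A and 92.7% to 114% with B. The Aux/IAA difference ran from 0.85 to 0.97 for IAA, -0.14 to -0.08 for A and -0.14 to -0.05 for B against DMSO, -0.11 to 0.016 (without IAA 2) for IAA plus A and 0.07 to 0.23 for IAA plus B against IAA, 0.92 to 1.03 for IAA plus A against A, where 6 arrays can no longer reach the threshold, 1.07 to 1.23 for IAA plus B against B, -0.065 to 0.033 (without B 3) for A against B and -0.28 to -0.12 for IAA plus A against IAA plus B. A block for the scan day and a pseudocount were not run.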

Other observations

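The families of genes sharing a symbol, 43 in number, were tested with camera only after the data were seen, in 9 comparisons. Camera made 43 calls in the 387 tests, of which 2 held with an estimated correlation: the IAA symbols, which are the Aux/IAA genes, in IAA plus A against A and IAA plus B against B (adjusted p = 0.00732 and 0.00699 with an estimated correlation). Calls that did not hold included, higher with A than with DMSO, PUB (adjusted p = 0.095 with an estimated correlation), CML and UGT (both 0.379), and with B, RPS and RPL higher (both 0.673), RALFL lower (0.471) and PRA lower (0.309). Genes of the plastid genome had positive medians in most comparisons. With B, 18 of 69 were higher than with DMSO (median 0.53; camera adjusted p = 6.23e-12), and 13 were higher in IAA plus B than in IAA (0.35; 6.17e-08). Camera also called the family in IAA against DMSO (4 higher and 1 lower; median 0.19; 6.30e-05), A against DMSO (0 past the threshold; 0.20; 0.00398), IAA plus A against IAA (9 higher; 0.16; 0.0019), IAA plus A against A (0 past the threshold; 0.25; 2.97e-08) and, lower with A, in A against B (4 lower; -0.31; 4.80e-05). None of these 7 calls held, at adjusted p = 0.646 to 0.958 with an estimated correlation.

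The residuals of 48 pairs of arrays with the same replicate number in different groups had a mean correlation of 0.05 across probe sets, against -0.02 for 135 pairs with different numbers, and ranged from -0.43 to 0.54. The DMSO and A arrays numbered 2, 3 and 4 correlated at 0.40, 0.24 and 0.54 and those numbered 1 at -0.06, so the numbers are no clear pairing over all groups, and a link between some arrays of the same number stays open. Among the RNA quality controls the lowest p was for the log2 GAPDH ratio of IAA plus A against IAA, a difference of -0.13 (exact permutation p = 0.0286, the smallest possible; 0.463 adjusted over 27 tests, a number at which no single difference could pass). The actin ratio was higher by 0.30 in B against DMSO (exact permutation p = 0.0857) and by 0.39 in IAA plus B against IAA (exact permutation p = 0.2). In these 2 comparisons the GAPDH ratio differed by -0.09 and -0.02, and the ubiquitin ratio by 0.02 and 0.11. All experiment files named 1 chip lot.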
